A study of Mus musculus with 24 samples.

How the data were processed

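The series holds 24 exome libraries, 1 from each of 24 clonal sublines that were grown from single cells of B2905, a mouse melanoma line from a C57BL/6 animal carrying an HGF transgene, per the labels. Coding DNA was captured with an Agilent mouse exon kit and the pooled libraries were sequenced on a HiSeq3000, per the labels' protocols. The submitters' processing notes name the builds GRCm38 and mm10, GATK, Trim Galore 0.6.5, STAR 2.7.3a, Picard 2.22.3 and RSEM 1.3.2, with no role for any of them. The annotation program, the variant filters and the way the sublines were joined are not given in the sources used here.

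The authors deposited 1 list without a header. Each row gives a transcript and gene, a position, the reference and variant bases, a consequence class and the change in every affected transcript. No column names a subline or gives a read count, an allele fraction, a quality or a genotype. Depth is therefore unknown, and no value below belongs to a single subline. The results planned before the data were examined that need calls or reads per subline were not analysed here: variants per subline, sharing between sublines, the tree, allele fractions, blocks of missing variants, and the tests of truncal against private variants. The substitution, neighbouring-base and consequence results were computed over the pooled list instead, which was decided after the list was seen. The plan for neighbouring bases took both sides of the cytosine from a genome sequence and set truncal against private variants; here the 5′ side alone was read, and C>T was set against C>A and C>G.

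Rows with the same position and bases were joined, so each variant counts once. The 16461 rows held 10209 distinct variants, and in each of them the consequence class was the same in all rows. A variant whose transcripts belong to several genes (50 variants) was given to the first symbol in alphabetical order, and to any of its genes in the gene list tests. The change printed for a variant is that of its first transcript in alphabetical order. Of 4587 gene symbols, 4484 matched a symbol and 15 a synonym in a RefSeq table of GRCm38.p6, which was used for the number of protein-coding genes per chromosome.

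Substitutions were folded to 6 classes by the pyrimidine of the base pair. No genome sequence was used. The base on the 5′ side of a mutated cytosine was read from the reference amino acid, the codon position and the reference base, and only where these leave 1 answer to whether it is a pyrimidine. In simulated codons all 5627 resolved sites were read right. The rule guarantees this, so it checks the code and not the annotation or the unresolved sites. Genes with 1 or 2 variants were compared with genes with 3 or more, a division chosen after seeing the list. So were the counts of transcript orders, the limit of 6 orders, and windows of 5 Mb with at least 20 variants, with 40% synonymous as the limit of a rich window.

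Shares were compared by two-sided Fisher's exact tests, and strands by two-sided exact binomial tests, with Benjamini-Hochberg adjustment within each family: 6 substitution classes, 7 gene lists, 21 chromosomes, 72 windows and 10 tests by transcript order. Variants of one gene are not independent, so 95% intervals come from 2000 resamplings of genes unless Wilson's method is named. They cover the sampling of genes and not errors of variant calling. Protein-changing means every class except synonymous. The list had no splice-site class. For the gene lists, simulated data without an effect gave 5 calls in 700 list tests. With the odds of a protein change multiplied by 0.33, the signalling list was called in 27 of 100 runs and the long-gene list in 100 of 100. Multiplied by 3, they were called in 0 and 100 of 100 runs. Each variant was drawn on its own, so these runs do not cover the dependence of variants within a gene.

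The genes named were fixed by a rule before the data were examined: per list, up to 6 genes with a protein-changing variant, first nonsense, then frameshift, then others, then by symbol, every nonsense or frameshift variant in a gene of any list (1 in the tumour suppressors, 1 in the chromatin regulators, 2 in DNA repair and 12 in the long genes, all in genes that the first part of the rule takes), and the 10 genes with the most protein-changing variants. The number of carrying sublines, which the rule also used, and its part on clades had no value here. Some genes that the rule takes are not reported here. The alternatives fixed beforehand were single-base substitutions only, leaving out variants within 10 bp of another, and leaving out genes by the start of their symbol (Olfr, Vmn, Muc, Zfp, Gm and digits, H2-, Krtap or Skint), taken to stand for genes with similar copies, which was not tested. Alternatives on read support, allele fraction, the definition of truncal, left-out sublines, tree methods and splice sites were not run. Alternatives added after seeing the data were genes with 1 or 2 variants only, without chromosome 13, without Gm10717 and, for the synonymous shares of chromosomes 4, 9 and 10, without the 5 Mb window with most variants, adjusted over those 3 tests. The 2 windows of chromosome 13 with most variants in many orders were also left out once. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.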

Results

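The deposited list pooled the coding variants of 24 clonal sublines of the mouse melanoma line B2905, each grown from 1 cell and sequenced as 1 exome library. It held 10209 distinct variants in 4554 genes, of which 9690 were single-base substitutions and 519 were insertions or deletions. The list does not say which subline carried a variant or how many reads showed it, so the depth is unknown and all values below are over the 24 sublines together, with no replicates. No control or normal tissue was among the samples. Positions are in GRCm38 (mm10), and changes of coding sequence and protein are counted from the start codon of the transcript used.

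Amino acid substitutions were the most frequent consequence, with 6672 variants, or 65.4% of the list (95% interval 63.9 to 66.7). Synonymous variants numbered 2782, or 27.3% (25.8 to 28.7). Stop codons were gained by 226 variants and lost by 24. Frameshifts came from 287 deletions and 82 insertions, and 116 deletions and 20 insertions kept the reading frame. Of the 82 frameshift insertions, 20 had a frameshift deletion of the same length within 10 bp in the same gene, so some pairs can be single replacements. Together 72.7% of variants changed the protein. In genes with 1 or 2 variants the synonymous share was 23.1% of 4745 variants.

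The genes of MAPK and receptor tyrosine kinase signalling with a protein change included a known oncogene of melanoma. Gnaq, a G protein subunit mutated in uveal melanoma, carried Q209L, its activating hotspot change, in exon 5 (chromosome 19, position 16335001). Protein changes were also listed in the receptor tyrosine kinases Egfr (C190Y), Epha7 (L569S) and Erbb4 (Y1266H and Y1056C), and in the RAS regulator Nf1 (T2806N). Of the 47 genes of this list fixed before the data were examined, 12 had a variant and 7 a protein change. Braf and Kit, kinases of the same pathway looked up after the values were seen, had 1 and 2 variants, all synonymous.

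Among 44 cell cycle, p53 and PI3K tumour suppressor genes, 18 had a variant and 14 a protein change. The atypical cadherin gene Fat1 carried a gained stop codon, W3662X, in exon 18 (chromosome 8, position 45037107), besides M1370T and D3153H. The DNA damage kinases Atm (Y1219H and N1096S), Atr (R861K and L2522Q) and Chek2 (L352V), the WNT regulator Apc (N434K) and Fat2 (L393V) carried amino acid substitutions. Among 41 chromatin regulators, 19 had a variant and 16 a protein change. Chd7, a chromatin remodeller, carried 2 substitutions, Y304C and H2060R, and a deletion listed as a frameshift (chromosome 4, positions 8832469 to 8832488). Of its 20 bases 14 are coding, so it runs over the edge of exon 14. Arid2 (W225R), Asxl1 (K353T), Atrx (F1895I) and Chd2 (F861V) carried substitutions.

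Among 50 DNA repair genes, 13 had a variant and 11 a protein change. Nbn, a part of the double-strand break sensor, carried the substitution K334M. It also held a deletion and an insertion of 5 bases each that met at position 15963773 of chromosome 4, at the edge of exon 3, where 2 of the deleted bases are coding. They are listed as 2 frameshifts, and whether they are 1 replacement of equal length is not given. Brca2 (R1926H), Ddb1 (N462S and M1054T), Ercc4 (Y752C) and Mlh3 (K1329T) carried substitutions. Among 36 melanocyte lineage genes, 7 had a variant and each of the 7 a protein change. They included the pigment transporters Slc24a5 (S402Y) and Slc45a2 (L185V), the melanosome trafficking genes Hps3 (L586M) and Lyst with 4 substitutions and 4 synonymous variants, and the transcription factors Tfap2a (T304A) and Tfap2b, whose stop codon was lost (X460R). Lyst and Tfap2a lie on chromosome 13, in 5 Mb windows with 61.1% and 52.4% synonymous variants, an excess described below. Among 47 antigen presentation and interferon genes, 3 had a variant. These were Casp8, an apoptosis protease (D439E), the class I gene H2-Q7 (Q194E, with a synonymous variant), whose reads can come from similar H2 genes, and Ifngr2 with a synonymous variant.

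None of the 7 lists passed the test for a different balance of protein-changing and synonymous variants, and 0 of 7 had an unadjusted p under 0.05. The signalling list held 8 protein-changing and 8 synonymous variants, against 72.8% protein-changing elsewhere (odds ratio 0.374, 0.138 to 1.14, Fisher's exact test, p = 0.0503, adjusted p = 0.352). The other odds ratios were 0.748 for tumour suppressors (20 against 10 variants), 1.05 for chromatin regulators (28 against 10), 1.37 for DNA repair (22 against 6), 0.588 for melanocyte lineage (11 against 7) and 0.374 for antigen presentation (2 against 2), with adjusted p from 0.70 to 1. Very long genes such as Ttn, taken as a passenger comparison, had 254 protein-changing and 94 synonymous variants (odds ratio 1.01, 0.588 to 1.35). Muc4 alone held 208 of these 348 variants, and in genes with 1 or 2 variants the odds ratio was 2.11 (adjusted p = 0.577). In such genes the ratio was 0.549 for chromatin regulators and 0.80 for DNA repair, and without chromosome 13, which holds 10 of the 18 melanocyte lineage variants, that list's ratio was 0.9996; none of these passed the test. The long genes included Ahnak2, Dnah8, Lrp1, Muc4 and Pkhd1l1, each with a gained stop codon or a frameshift. With odds raised 3-fold in data simulated variant by variant, the long-gene list was called in 100 of 100 runs and the chromatin list in 49. The DNA repair list was called in 22, tumour suppressors in 20, melanocyte lineage in 9, and signalling and antigen presentation in 0. At this number of variants a rise of that size was not detectable in the last 2 lists. It would mostly be missed in the DNA repair, tumour suppressor and melanocyte lists.

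Variants were crowded in few genes. The 10 genes with the most protein-changing variants were Gm10717 (271), Muc4 (157), Gm10719 (138), Gm11168 (108), Gm21738 (93), Vmn2r115 (90), Gm10722 (88), Mroh2a (83), Vmn2r117 (77) and Nop2 (72). Together with their synonymous variants these genes held 1577 variants, 15.4% of the list. Gm10717 alone had 322 variants within 7329 bp of chromosome 9, and the first 5 Mb of that chromosome held 1043 variants in 10 genes, most of them predicted genes. Muc4, a repeat-rich mucin, had 208 variants. Predicted genes named Gm made up 19.1% of all variants, vomeronasal receptors 6.63%, zinc finger genes named Zfp 3.72%, olfactory receptors 2.81% and mucins 2.60%. Gm is a name for predicted genes and not a family. Where genes have similar copies or repeats, reads can be placed on the wrong copy, and sequence identity was not tested here. The small ribosome biogenesis gene Rrs1, singled out after its values were seen, had 54 variants within 1012 bp. In contrast, 3365 genes had a single variant, and 30.8% of all variants lay within 10 bp of another.

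Substitutions are written by the pyrimidine of the base pair. T>C changes were the most frequent class, with 31.0% of substitutions (29.2 to 33.0), and C>T changes came second with 25.1% (23.8 to 26.7). The classes differed between sparsely and densely hit genes. In genes with 1 or 2 variants, T>C made up 38.8% of 4493 substitutions, against 24.2% of 5197 in genes with 3 or more (odds ratio 1.98, 1.74 to 2.24, Fisher's exact test, adjusted p = 6.15e-53). C>T made up 18.5% and 30.9% (odds ratio 0.508, 0.442 to 0.582, adjusted p = 1.17e-44). C>A was also rarer in the sparsely hit genes, at 8.41% against 13.5% (adjusted p = 1.64e-15), and T>G was more frequent, at 14.4% against 10.7% (adjusted p = 6.26e-08). The interval with genes resampled included 1 for C>G (odds ratio 1.14, adjusted p = 0.0812) and for T>A (0.849, adjusted p = 0.0116).

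**Figure D1:**
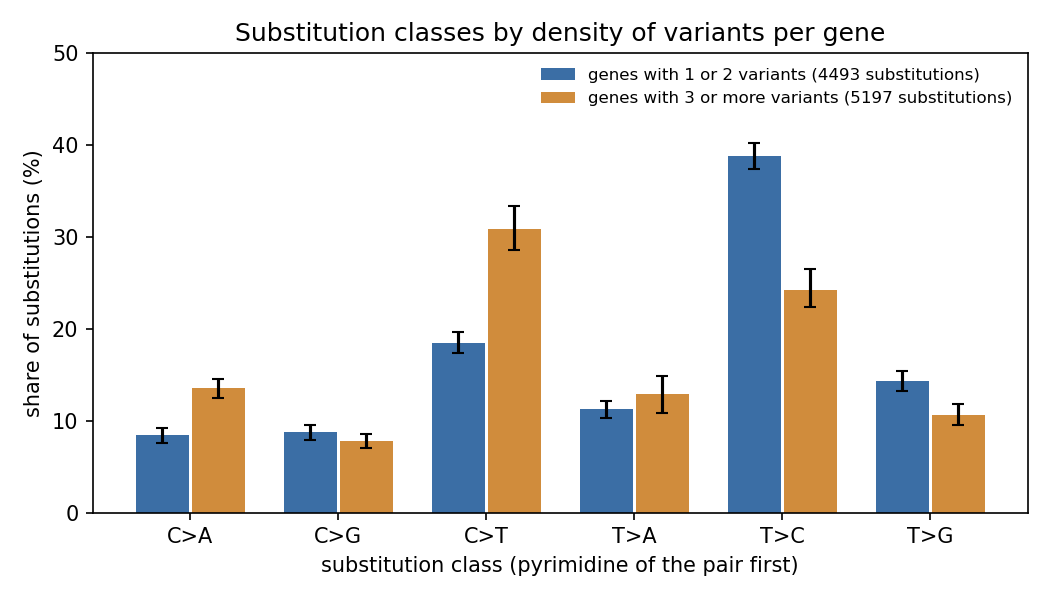
Share of single-base substitutions (percent, vertical axis) in each of the 6 classes (horizontal axis), for genes with 1 or 2 listed variants and for genes with 3 or more; bars start at 0 and error bars are 95% intervals from resampling genes. T>C reaches 38.8% in the sparsely hit genes, and C>T reaches 30.9% in the densely hit genes.

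Cytosines changed to thymine followed a pyrimidine more often than cytosines with another change. C>T next to another pyrimidine is the textbook mark of ultraviolet light, but the cause of these changes was not tested here. Of 1340 C>T sites at which the codon fixed the base on the 5′ side, 48.8% had a pyrimidine there (46.2 to 51.5). The share was 40.1% of 1007 sites of C>A and C>G (36.9 to 43.1; odds ratio 1.42, 1.21 to 1.67, Fisher's exact test, p = 3.3e-05). In genes with 1 or 2 variants it was 50.9% against 34.8% (odds ratio 1.94, 1.48 to 2.57, p = 1.71e-06). In genes with 3 or more it was 47.7% against 43.9%, which did not pass the test (odds ratio 1.17, 0.968 to 1.40, p = 0.165); the difference between the sets of genes was not tested. Of 694 pairs of substitutions at neighbouring bases, 26 were CC-to-TT changes (3.75%, Wilson interval 2.57 to 5.43). In genes with 1 or 2 variants 2 of 18 were, in Bnip3l and Mbd5, named after their values were seen (11.1%, 3.1 to 32.8). The codon fixed the base for 55.0% of C>T sites, and CpG sites could not be set apart.

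Complementary changes were not listed equally often on the coding strand of genes; the base composition of the strands was not used here. A>G on the coding strand numbered 1580 and T>C 1421, so that 47.4% of the class had T on the coding strand (44.97 to 49.8, exact binomial test, adjusted p = 0.012). In genes with 1 or 2 variants the share was 44.4% of 1742 (42.0 to 46.7, adjusted p = 1.75e-05). There T>G had a similar share, 43.4% (adjusted p = 0.00278), and the share with A on the coding strand did not differ detectably between T>C and the other changes of T (55.6% and 53.8%, odds ratio 1.08, 0.93 to 1.25, Fisher's exact test, p = 0.34). C>T on the coding strand numbered 1289 against 1146 G>A, a share of 52.9% (50.7 to 55.1, adjusted p = 0.012). The ratio of 1.12 fell to 1.058 without variants within 10 bp of another and to 1.068 without the families left out by symbol, and neither passed (exact binomial test, p = 0.275 and 0.209). In genes with 1 or 2 variants the share was 52.7% and did not pass the test with 438 against 393 (adjusted p = 0.254).

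Chromosome 13 stood apart in its synonymous variants. They made up 50.6% of its 902 variants (45.8 to 55.3), against 24.99% on the other chromosomes (odds ratio 3.07, 2.501 to 3.77, Fisher's exact test, adjusted p = 1.89e-53). The variants lay in stretches rather than along the whole chromosome. The genes named here were chosen after their values were seen. The window from 20 to 25 Mb held 203 variants in 67 genes, with 60.6% synonymous, among them the iron regulator Hfe, histone genes and olfactory receptors. The window from 95 to 100 Mb held 125 variants in 23 genes with 63.2% synonymous, led by Iqgap2 and the thrombin receptor family gene F2rl1, with 16 of 24 and 13 of 17 variants synonymous. Naip1, Naip5, Naip2 and Naip6, inflammasome sensors of 1 gene family, held 114 variants between positions 100154951 and 100444540. The 3 windows between positions 80000001 and 95000000 held 5, 3 and 7 variants. Chromosomes 4, 9 and 10 had lower synonymous shares than the others, 21.5%, 21.3% and 17.7% (Fisher's exact test, adjusted p = 0.00393, 4.13e-07 and 0.000403). The others include chromosome 13, which raises their share, and these tests were not rerun without it. On chromosome 9 the call was lost without the first 5 Mb, since 24.9% of the 361 variants outside that window were synonymous (odds ratio 0.846, 0.558 to 1.26, Fisher's exact test, adjusted p = 0.189).

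Relative to its protein-coding genes, the Y chromosome had the most variants, 151.2 per 100 genes, followed by chromosome 9 with 116.9 and chromosome 13 with 108.8. The X chromosome had the fewest, 20.4. These densities were not tested. Counting genes with 1 or 2 variants only, the Y chromosome had 6.64 and chromosome 9 had 21.3 variants per 100 genes, and chromosome 13 had 27.3. Of the 387 variants on the Y chromosome, the predicted genes Gm21820, Gm20918, Gm20830 and Gm21719 held more than any other gene, with 63, 43, 30 and 29. Among genes not named Gm, 23 variants lay in the sex-determining gene Sry, 22 in Usp9y, 15 each in Uba1y and Zfy2, and 14 in Zfy1. All these genes were named after their values were seen.

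**Figure D2:**
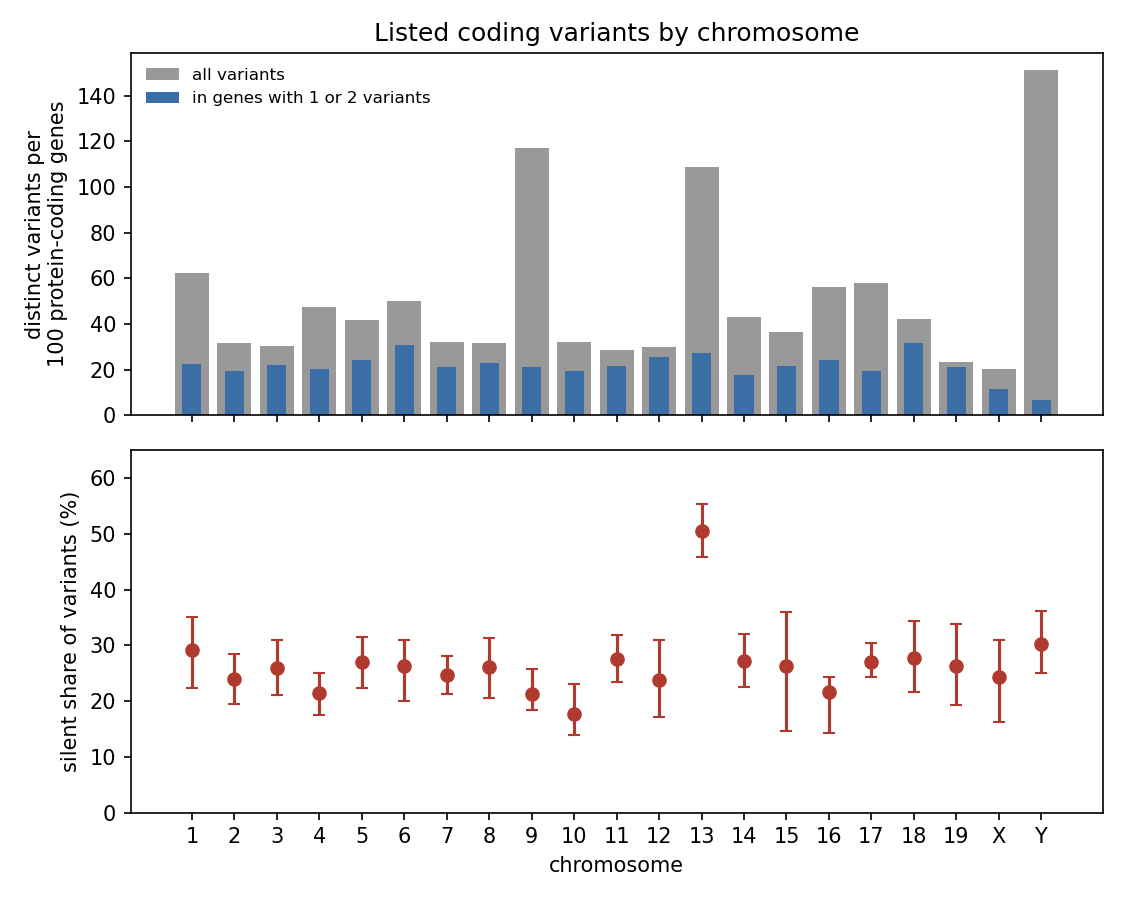
Upper panel, distinct variants per 100 protein-coding genes of each chromosome, for all variants (grey) and for genes with 1 or 2 variants (blue); lower panel, synonymous (silent) share of variants in percent with 95% intervals from resampling genes. Chromosome 13, at 50.6%, lies above the other 20 chromosomes.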

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

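All tests in this part were chosen after the pattern was seen. The list repeats variants in a way that none of the comparisons above uses: 1847 variants stand in more than 1 row, and these rows differ in the order in which the same transcripts are written. The highest number of orders of 1 variant was 25, reached by 56 variants, and 379 of the 1665 variants with 3 or more transcripts were in 6 or more orders. The orders were shared between variants. The 22 variants of the Ugt1a cluster with the same 12 transcripts filled 544 rows with 25 orders, and 48 such shared sets of 5 or more transcripts had 559 distinct orders in 2512 rows. A new random order for every row would have given 1863 to 1903 in 100 simulations, which argues against it. No shared set exceeded 25 orders, so a candidate explanation is that each order marks a separate annotation run, 1 more than the 24 sublines. Which library each run belongs to stays open, and no biological explanation was tested.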

How the results depend on the processing

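The alternatives without chromosome 13, without Gm10717, with sparse genes (1 or 2 variants) only, and without the 5 Mb window with most variants of chromosomes 4, 9 and 10 were chosen after the results were seen. Of 92 recomputed values, 5 could not change, since substitutions only is already the set they use. Of 23 others for results that passed their test, 19 still passed in the same direction. Of 42 for gene lists, which did not pass under any alternative run, 35 kept their side of 1, which says little for the short lists. Of 22 for values with no test, 9 stayed within the 95% binomial interval or, for counts, within 1.5 times. The call on 5′ pyrimidines (odds ratios 1.42 to 1.94), that on A>G over T>C (ratios 1.11 to 1.25) and that on synonymous variants of chromosome 13 (odds ratios 2.31 to 3.45) held under the other alternatives that were run. The number of variants fell to 6629 without the named families and to 4745 in genes with 1 or 2 variants. The C>T share moved to 23.01% without variants within 10 bp of another, 24.2% without the families, 24.2% without chromosome 13 and 18.5% in genes with 1 or 2 variants; both values of 24.2% lie within the wider interval from resampled genes. The T>C share moved to 35.9%, 35.1% and 38.8% under the close-variant, family and sparse-gene alternatives. The ratio of C>T to G>A on the coding strand, 1.12 in the full list, no longer passed at 1.058 without close variants, 1.068 without the families and 1.115 in sparse genes (p = 0.275, 0.209 and 0.127). The sparse-gene ratio is close to that of the full list and has fewer variants behind it; for the other 2 alternatives the cause was not tested. The protein-changing share moved to 71.3% for substitutions only, 71.2% without the families, 76.9% in sparse genes and 75.0% without chromosome 13. The low synonymous share of chromosome 9 no longer passed without its first 5 Mb (odds ratio 0.846, Fisher's exact test, adjusted p = 0.189), an alternative that leaves out 1043 of its 1404 variants. Those of chromosomes 4 and 10 still passed at 0.735 and 0.619. Each was set against chromosomes that include chromosome 13 and was not rerun without it, so these calls can lean on its excess. The shares left on chromosomes 4 and 10 were 21.9% and 19.1%, against 24.99% outside chromosome 13, a comparison that was not tested. 3 gene lists changed the side of 1. Chromatin regulators went to 0.966 for substitutions only, 0.980 without close variants and 0.549 in sparse genes. DNA repair went to 0.80 in sparse genes. Long genes went to 0.901 without close variants, 0.856 without the families and 0.9996 without chromosome 13, and rose to 2.11 in sparse genes. Melanocyte lineage went from 0.588 to 0.9996 without chromosome 13. The cause of these moves was not tested. No paired analysis was possible because the columns name no subline. Read support, allele fraction, the definition of truncal, left-out sublines, distance and tree methods, and splice-site classes were not run, since the list gives no calls per subline, and without depth no limit of detection can be given.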

Other observations

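The tests in this part were all chosen after the patterns were seen, and they read the number of transcript orders of a variant as a rough count of the annotation runs that held it. This is a hypothesis, it can be read for the 16.3% of variants with 3 or more transcripts, and 3 transcripts allow 6 orders at most, so a variant of 2 runs can appear in 1 order. Fat1 W3662X was in 4 orders, Fat1 D3153H in 3 and Fat1 M1370T in 1. Epha7 L569S and Chd7 Y304C, with 4 and 3 transcripts, were each in 1 order. Casp8 D439E was in 2 orders, Mlh3 K1329T in 6 and H2-Q7 Q194E in 18. Gnaq Q209L has 1 transcript and cannot be read. Of 6 gained stop codons in many orders, 3 lay in Trps1 (R387X, 23 orders), a GATA-type transcription factor, Fmn1 (Q629X, 24 orders), a formin, and Npm1 (S4X, 12 orders), a nucleolar protein. The other 3 lay in Olfr1369-ps1 (I145X, 21 orders), named as an olfactory receptor pseudogene, in the olfactory receptor gene Olfr44 (I307X, 6 orders) and in Pgbd1 (Q206X, 6 orders). I145X and I307X are deletions of 1 base (433delA and 919delA) that are listed as gained stop codons. Within 10 bp of I145X lay a frameshift deletion (436delG), also in 21 orders. Tfap2a T304A was in 23 orders, and 5 substitutions of the translesion polymerase Polk were each in all 6 orders of their 3 transcripts; both genes lie in synonymous-rich windows of chromosome 13. Ttn, the sarcomere giant, had 3 substitutions in 13 orders each. Of 388 variants with 5 or more transcripts, 207 were in 1 order, 115 in 20 or more, and 66 in between.

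T>C made up 45.5% of 964 substitutions in 1 order (42.3 to 48.8) and 25.8% of 364 in many (odds ratio 2.40, 1.82 to 3.28, Fisher's exact test, adjusted p = 6.94e-11), while C>T made up 13.2% and 39.3%; with 5 or more transcripts T>C made up 49.5% and 23.6%. The difference in T>C was not confined to crowded genes and the named families. In genes with 1 or 2 variants outside these families T>C stayed at 46.9% (42.9 to 50.8) against 27.9%. T>C is more frequent in such genes in the whole list, so this filter was not likely to lower its share. It therefore does not decide on misplaced reads as a cause. Sequence identity was not used, so misplaced reads within the remaining genes stay open. RNA editing is not read in libraries of captured coding DNA, as these are per the labels' protocols. It would also put A on the coding strand in nearly all cases, and the share was 56.3% (51.4 to 61.0). A process acting through the whole history of the line is argued against as the whole cause, since T>C made up 22.4% (17.35 to 28.1) of substitutions in 2 to 5 orders. Such a process beside errors in single libraries stays open, since those errors would add to the variants in 1 order alone. Errors in single libraries and mutations that arose after the sublines parted cannot be told apart, since no read counts are given. Of the 591 readable T>C substitutions 74.3% were in 1 order, as were 1008 of all 1665 readable variants.

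The synonymous variants of chromosome 13 may come from segments inherited from another mouse strain. Of its 137 variants in many orders, 56.2% were synonymous, against 30.6% of 242 elsewhere (odds ratio 2.91, 1.55 to 5.27), which repeats the excess in a subset of the variants. Misplaced reads in crowded genes and the named families are argued against as the whole cause by genes with 1 or 2 variants outside these families. There 39.6% were synonymous (32.8 to 46.7) against 22.2% elsewhere. Misplaced reads within the remaining genes were not tested. The 9 windows of 5 Mb with at least 20 variants and over 40% synonymous held 130 variants in many orders and 19 in 1 order, against 7 and 18 in the other 16 windows of the chromosome (odds ratio 17.6, 5.58 to 121, Fisher's exact test, p = 2.64e-09); 100 of the 130 lay in 2 windows, without which the odds ratio was 7.71 (2.04 to 44.8, p = 0.000285), and 3 of the 9 held no more variants in many orders than in 1. These windows were picked by synonymous share. Outside chromosome 13 that share is also higher in many orders than in 1 (32.0% and 21.8% of substitutions). Early somatic mutations would be in many orders too, so the orders do not part them from inherited segments. Somatic mutations with the synonymous share seen elsewhere are argued against as the whole cause. That share was 24.99% on the other chromosomes, against 50.6% on chromosome 13 (45.8 to 55.3). With no strain sequence used, inherited segments and somatic mutations with another synonymous share cannot be told apart.

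Of 72 windows of 5 Mb with at least 20 variants outside the named families, 13 had an excess of synonymous variants at an adjusted p under 0.05 (Fisher's exact test), 9 of them on chromosome 13. Of the other 4, 3 lay on chromosome 1, where Mroh2a alone held 68 of the 122 synonymous variants, on chromosome 5 with Cyp3a genes, and on chromosome 15 with keratin genes. These tests take variants of 1 gene as independent, and no interval from resampled genes was computed for the windows.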
